A study of Mus musculus with 6 samples.

How the data were processed

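PolyA RNA sequencing libraries of brown adipose tissue from C57BL6 mice were compared, 3 wild-type against 3 AdIl17rc knockout libraries, grouped and numbered as the labels give them. The authors deposited a single table of FPKM values (fragments per kilobase of transcript and per megafragment mapped), with 24043 rows and 6 sample columns. STAR 2.5.1b, Cufflinks 2.2.1 and DESeq2 1.10.1 are named in the submitters' processing notes, with mouse build mm9. The gene annotation, strand setting, treatment of reads with several matches and any bias correction are not given in the sources used here. The table is described by its name as counts, but its values were not whole and the value of a single read fell with transcript length, as for FPKM, so no count model was used. A workbook had turned 27 symbols into dates, and those rows were left out. No other symbol stood on more than 1 row.

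FPKM keeps no library totals. Depth was approximated from the value of a single read among low values of genes with 1 annotated transcript, which gave about 31.2 to 38.4 megafragments per library, and the depth relative to wild-type library 1 was between 0.942 and 1.16. An exact 0 in such a table can be a failed estimate, so genes at 0 are said to be listed at 0. The 10 features with the highest values made up 12.3% to 15.7% of the FPKM sum in 5 libraries and 44.4% in knockout library 2, where the feature Mir6236 alone was at 146487 FPKM.

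Values were tested as log2(FPKM + 0.5) for the 10864 genes with a mean FPKM of at least 0.5 over the 6 libraries, with limma 3.58.1 in R 4.3.3 (linear model on genotype, empirical Bayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale, which understates the change of low genes. No scaling between libraries and no replicate block was applied in that test. The labels name no pairs. With group means removed, wild-type and knockout libraries of the same number correlated at 0.10, -0.12 and -0.081 for numbers 1, 2 and 3. The wild-type library most like knockout libraries 1, 2 and 3 was 1, 3 and 2. A call lost with a replicate block therefore does not show a pair or batch effect. Because the median gene was shifted, changes relative to it were taken from the same fit after median-of-ratios scaling, with factors of 1.33, 1.02 and 1.05 for wild-type libraries 1, 2 and 3 and 1.00, 0.849 and 0.836 for knockout libraries 1, 2 and 3. Exact two-sided permutation tests of 3 against 3 values cannot go below p = 0.1.

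In total 28 gene lists for pathways and cell types, and a list of sex-linked markers used only as a check of the samples, were fixed before the data were examined. Lists with at least 3 tested members (26 of 28) were tested with camera (limma) at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Named genes followed a rule fixed at the same time: Il17rc, Il17ra, Tgfb1, Ucp1, Th and Adipoq; up to 10 genes per direction at a mean FPKM of at least 1, those past the threshold with groups that do not overlap first, by log2 fold change, and then those with the smallest p; and up to 4 members per list with the smallest p. Predicted genes and small RNA features were left out of the second part but counted. Some genes that the rule names are not reported here.

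GC content and transcript length came from an annotation of another mouse build (GRCm38), used only for names, length, GC content and the order of neighbouring genes; 22633 of 24041 distinct entries, the dates among them, matched directly and 922 through an older name. A value was available for 10802 tested genes (99.4%), and the correction fitted natural splines of GC content and log2 length with 4 degrees of freedom each per library.

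The test was checked on simulated libraries drawn from the scaled means and spread of the 10864 genes, with 200 changed genes in each of 10 runs. It recovered 88.1% of genes changed by 1 log2 unit and 98.3% of genes changed by 2, 4.85% of its calls were false, and 1 of 260 lists without an effect was called. The simulated genes were drawn independently of each other and without shifts between libraries. Their spread was the one left after empirical Bayes, which varies less between genes than the raw spread. The recovered shares can therefore be too high for the real libraries. In the real scaled fit Scd3 (log2 fold change -1.63) and Irf7 (1.66) did not pass (limma adjusted p = 0.170 and 0.203). In the real libraries the lists had estimated inter-gene correlations of 0.18 to 0.94, so the simulation does not show how often camera calls such lists falsely. Its rates also need not hold for the test on the deposited scale. The alternatives tried were pseudocounts of 1 and 0.1, other filters, other scalings, other variance models, a replicate block, a threshold of 0.1 and each library left out in turn; GC and length correction, and leaving out knockout libraries 1 and 2 or small RNA features, were added after seeing the data.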

Results

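Gene expression was measured by polyA RNA sequencing in brown adipose tissue, the heat-producing fat depot, of C57BL6 mice. The 6 libraries fell into 2 groups: 3 labelled wild type and 3 labelled AdIl17rc KO, a knockout that the series title ties to the IL-17 receptor subunit IL-17RC of adipocytes. The deposited table held FPKM values on 24043 lines, 1 gene symbol each. Depth was not listed and was approximated from low values and transcript lengths, which gave 32.9, 38.4 and 36.2 megafragments for wild-type libraries 1, 2 and 3 and 31.2, 32.7 and 36.0 megafragments for knockout libraries 1, 2 and 3. The labels did not say that the libraries came from separate animals, so p-values measure only the spread between these samples. Pearson correlations of log2(FPKM + 0.5) over tested genes ran from 0.964 to 0.974 within wild type, from 0.957 to 0.973 within knockout and from 0.943 to 0.966 between the groups. The leading principal component held 48.0% of the variance and placed every wild-type library on one side of 0 and every knockout library on the other. Wild-type library 1 led it: the scores were -53.2, -9.17 and -8.29 in wild-type libraries 1, 2 and 3 and 8.11, 31.5 and 31.1 in knockout libraries 1, 2 and 3. On this component alone knockout library 1 lay nearer to wild-type libraries 2 and 3 than to the other knockout libraries. After scaling to the median gene the share was 34.2% and that position was lost. The scaled scores were -34.7, -15.4 and -9.03 in wild-type libraries 1, 2 and 3. They were 17.7, 26.9 and 14.5 in knockout libraries 1, 2 and 3, so knockout library 1 lay between the other knockout libraries. The Y-linked gene Ddx3y was at 16.7 to 22.4 FPKM over the 6 libraries.

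Il17rc, the targeted gene, was lower in all 3 knockout libraries than in any wild-type library. Wild-type libraries 1, 2 and 3 held 3.21, 2.28 and 2.02 FPKM, and knockout libraries 1, 2 and 3 held 1.32, 0.619 and 0.530 FPKM, a mean of 2.51 ± 0.624 (SD, n = 3) against 0.822 ± 0.431. The log2 fold change was -1.21 ± 0.25 (SE, n = 3 per group), with a limma adjusted p of 0.151 over all genes, which did not pass 0.05 (-0.98 ± 0.19 scaled to the median gene). It passed by limma after rescaling each library to a common sum (adjusted p = 0.00243). In knockout library 2 that sum was 383558 FPKM, of which the feature Mir6236 alone held 146487, so rescaling lowered its other genes. Il17rc also passed with limma sample quality weights, whose estimation stopped before converging (log2 fold change -1.19, adjusted p = 0.000935). Those weights were 4.94 for wild-type library 3, 6.82 for knockout library 2 and 0.192 to 0.859 for the others, so that fit rests mainly on this pair. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Il17ra, the partner receptor subunit, was at 4.63 ± 1.44 FPKM (SD, n = 3) in wild type and 3.10 ± 0.927 in knockout, with an adjusted p of 0.218 by limma; its log2 fold change was -0.50, -0.21 scaled and 0.00945 after a further GC and length correction, where the sign turned.

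**Figure D1:**
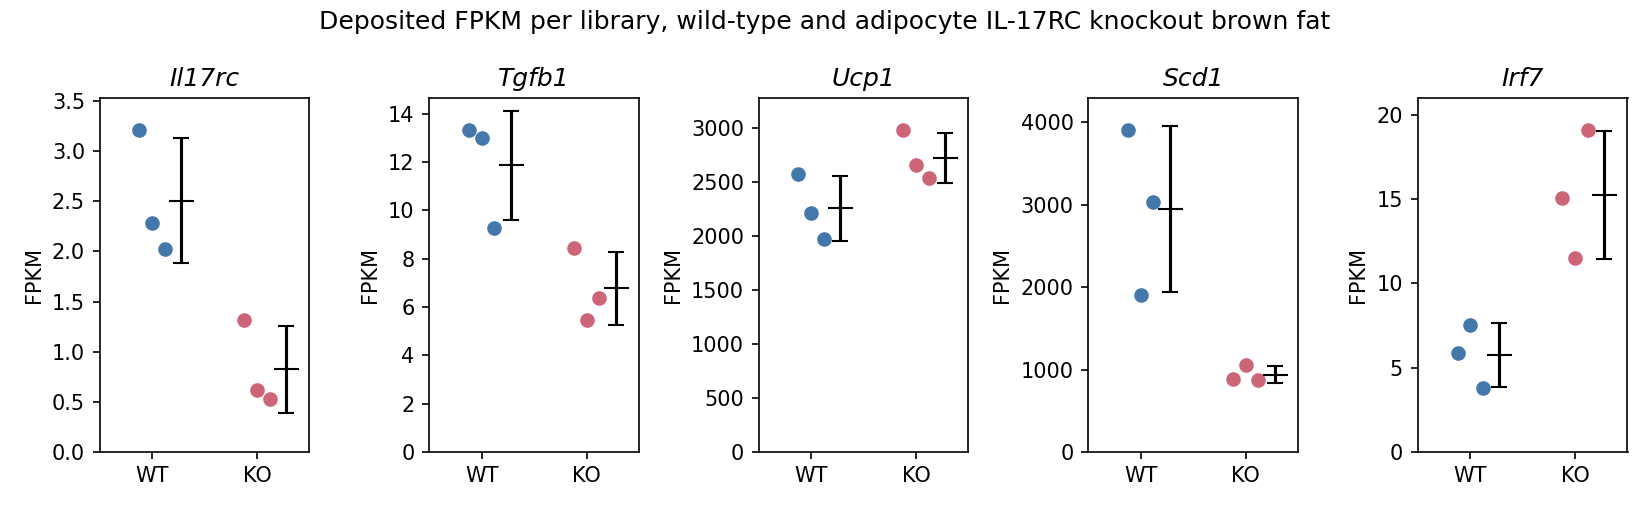
Deposited FPKM (y axis, from 0) of 5 genes in each wild-type (WT) and knockout (KO) library; points are libraries and the black mark with bars is the mean ± SD of 3 libraries. Il17rc lay at 2.02 to 3.21 FPKM in wild type and 0.530 to 1.32 in knockout, and Scd1 and Tgfb1 were likewise lower in every knockout library.

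Across all genes most values were lower in knockout: 1348 genes had a higher and 9516 a lower mean on the log scale, against 5393 and 5471 after scaling. Of 10864 tested genes, 1 was called higher (Snord32a) and 1 lower (Apoo-ps, a pseudogene of the mitochondrial protein gene Apoo) at an adjusted p under 0.05 by limma. Snord32a fell outside the rule for named genes and was chosen after its values were seen: it was listed at 0 in all wild-type libraries and at 333, 157 and 143 FPKM in knockout libraries 1, 2 and 3. Apoo-ps was at 58.1, 23.5 and 10.2 FPKM in wild-type libraries 1, 2 and 3 and at or next to 0 in every knockout library. The Apoo-ps call was lost with no filter (limma adjusted p = 0.255), with robust limma (0.093) and with a replicate block (0.0519). After scaling it was kept (0.0298), but lost with a replicate block (0.223) or without wild-type library 2 (0.077), knockout library 1 (0.133) or knockout library 2 (0.123). At an unadjusted limma p under 0.05 there were 110 higher and 2692 lower genes. The 2 groups did not overlap for 3581 genes (33.0%), and for 2759 (25.4%) after scaling, where chance gives 10%. The median gene had a log2 fold change of -0.29, so changes below are also given relative to it, from the same fit after median-of-ratios scaling ("scaled"). After scaling the calls were again 1 higher and 1 lower, with 983 higher and 935 lower genes at an unadjusted limma p under 0.05. The count depended on single choices. It was 300 (51 higher, 249 lower) when each library was rescaled to a common sum, which Mir6236 raised in knockout library 2. It was 14 (1 higher, 13 lower) with robust limma and 1 (higher) with a replicate block or no filter. With sample quality weights, which put most weight on wild-type library 3 and knockout library 2, it was 6382 (411 higher, 5971 lower). It was 4, 8 and 7 without wild-type libraries 1, 2 and 3, and 3 and 4 without knockout libraries 1 and 2. Without knockout library 3 it was 77, with the muscle markers Acta1 and Actn3 among them, and muscle transcripts were high in knockout libraries 1 and 2. Without knockout libraries 1 and 2, an alternative chosen after seeing the data, it was 13. That count rests on 1 knockout library assumed to vary like the wild-type libraries, the source of all the spread. Scaled fold changes also followed GC content across genes (Spearman rho -0.44), and genes are not independent replicates.

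Camera called 11 of 26 tested lists (6 higher, 5 lower), 0 of them with an estimated correlation. Fry called 0 as deposited and 2 scaled, the TGF-beta pathway and T cell markers, both as lower (fry adjusted p = 0.0491 for each). Apart from predicted genes and small RNA features such as Snord32a, which this choice leaves out, the 10 genes with the smallest p in each direction were taken, and of these only Apoo-ps passed over all genes in the test of the 6 libraries as deposited (limma adjusted p from 0.0901 to 0.151 for the others), a call lost with a replicate block (0.0519), no filter or robust limma. The higher genes were Kng1 (kininogen, 3.32 ± 0.43 against 7.08 ± 1.17 FPKM, mean ± SD, n = 3), the sodium-potassium-chloride cotransporter gene Slc12a2 (11.1 ± 1.8 against 18.7 ± 1.5), Gmpr (284 ± 32 against 417 ± 10), Tmed5 and the interferon-response genes Irf7, Mx2, Ifit3, Rsad2, Ifit1 and Isg15. The lower genes were Nav2 (3.66 ± 0.35 against 1.21 ± 0.18 FPKM), the desaturase genes Scd2, Scd3 and Scd4, the actin regulators Palld and Ssh1, Hr, Rhou and Creb3l2. Nav2 came nearest, with an adjusted p of 0.0901 by limma and a log2 fold change of -1.29 ± 0.16 (SE). With rescaling to a common sum, 7 of the 10 higher and all 9 of these lower genes passed. Mir6236 raised that sum in knockout library 2. With robust limma 0 and 8 passed. With sample quality weights, which put most weight on wild-type library 3 and knockout library 2, 10 and 9 passed. Without wild-type library 2 Scd3 and Scd4 passed, without knockout library 3 Nav2, Ssh1, Scd2, Scd3 and Scd4, and after scaling Kng1 without knockout library 1 (limma adjusted p = 0.0158) and Nav2 without knockout library 3 (0.0476).

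Interferon-response genes, which cells switch on during antiviral signalling, were higher in knockout for 22 of 22 tested members. Their median log2 fold change was 0.96 (1.18 scaled), and 13 rose when adjusted over the list alone (18 after scaling), against 0 over all genes. Irf7, a transcription factor of the response, was at 5.74 ± 1.90 FPKM (SD, n = 3) in wild type and 15.2 ± 3.8 in knockout, and Rsad2 was at 6.18 ± 2.95 and 23.3 ± 15.0. The list was higher than other genes by camera with a preset correlation (adjusted p = 9.95e-42), and the call was lost with an estimated correlation (adjusted p = 0.502). The libraries were uneven. Ifit1 was at 3.06, 5.98 and 1.20 FPKM in wild-type libraries 1, 2 and 3 and at 8.62, 9.45 and 25.6 FPKM in knockout libraries 1, 2 and 3, and the scaled median of the list stood 2.01 log2 units above the wild-type mean in knockout library 3 against 0.73 and 0.99 in knockout libraries 1 and 2.

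**Figure D2:**
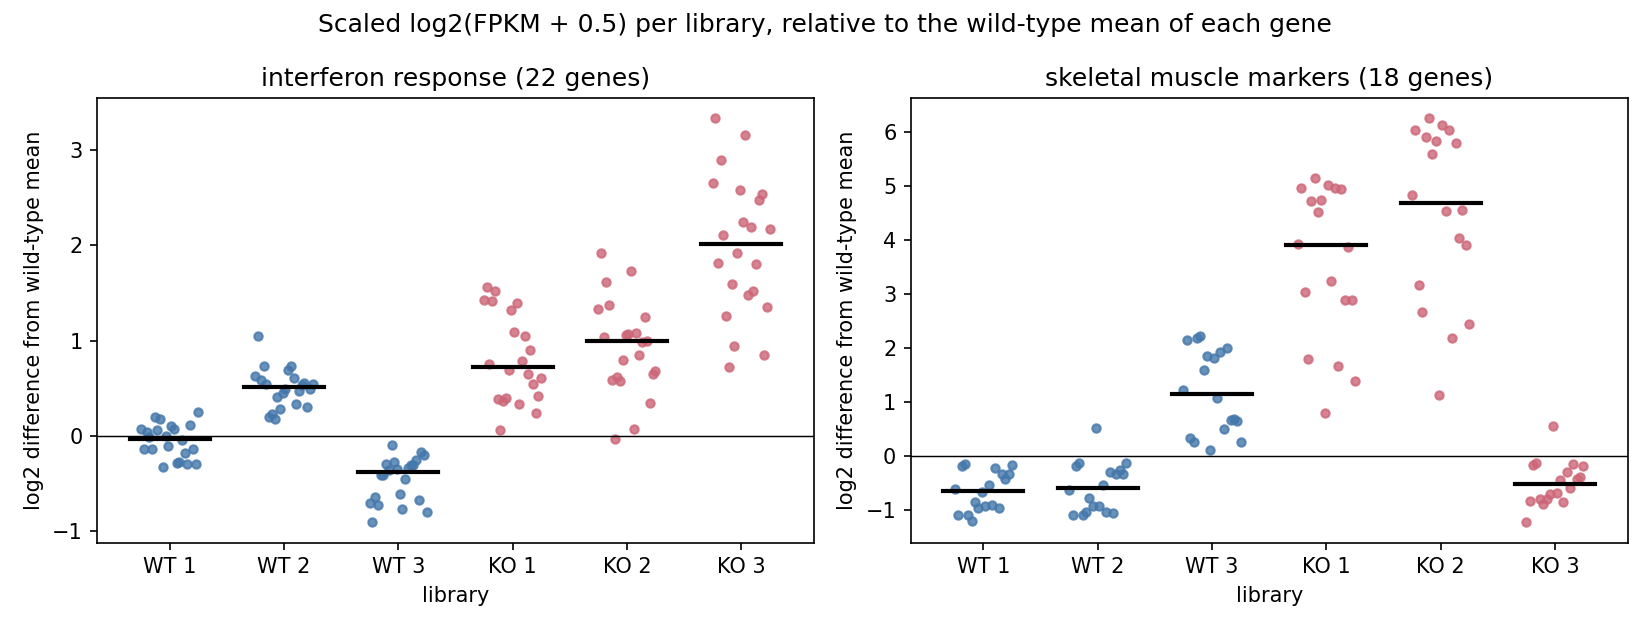
Scaled log2(FPKM + 0.5) of each tested interferon-response gene (left) and skeletal muscle marker (right) minus that gene's wild-type mean (y axis), by library (x axis); points are genes and black lines are medians. Interferon genes were highest in knockout library 3 (median 2.01), and muscle markers were high in knockout libraries 1 and 2 and not in knockout library 3.

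Most genes of fatty acid synthesis had lower values in knockout, 18 of 20 tested as deposited and 15 after scaling, where 5 were higher. Of all 10864 tested genes, 9516 were also lower as deposited. Of 20 tested members of the de novo lipogenesis list, 11 fell when adjusted over the list alone and 0 over all genes. After scaling 7 fell and 2 rose, and after a further GC and length correction 4 fell and 2 rose. Scd1, the main fat-tissue stearoyl-CoA desaturase, was at 2947 ± 1006 FPKM (SD, n = 3) in wild type and 937 ± 105 in knockout (scaled log2 fold change -1.26 ± 0.21 SE). Fatty acid synthase, Fasn, went from 91.5 ± 43.3 to 27.3 ± 8.5 FPKM, and Aacs, which activates acetoacetate for lipid synthesis, from 21.7 ± 3.1 to 9.77 ± 2.28. Scd1 to Scd4 are close relatives that can share reads, so the split between them is uncertain. The list was lower by camera (adjusted p = 0.012), and the call was lost with an estimated correlation (adjusted p = 0.942), with a replicate block (adjusted p = 0.158) and without wild-type library 3 (adjusted p = 0.0544).

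Most genes of the TGF-beta pathway and of the extracellular matrix had lower values in knockout. As deposited, so did 9516 of all 10864 tested genes. Of 21 tested matrix genes, 20 were lower as deposited and 17 after scaling. All 22 tested TGF-beta members had a negative log2 fold change (median -0.48, -0.20 scaled), of which 7 fell when adjusted over the list alone and 0 over all genes. After scaling 18 of the 22 were negative and 4 fell, and after a further GC and length correction the median was -0.0906, 3 fell and the camera adjusted p was 0.0424. The ligand gene Tgfb1 was at 11.9 ± 2.2 FPKM (SD, n = 3) in wild type and 6.76 ± 1.52 in knockout (log2 fold change -0.77 ± 0.21 SE, -0.46 scaled, -0.33 with GC and length correction, limma adjusted p = 0.151). Thbs1, a matrix protein that activates latent TGF-beta, went from 101 ± 33 to 36.1 ± 6.3 FPKM and the receptor gene Tgfbr2 from 29.8 ± 7.2 to 15.6 ± 0.6. Of 21 fibroblast and matrix genes, 13 fell when adjusted over the list alone, 4 after scaling, 0 after a further GC and length correction and 0 over all genes. Col1a1 went from 12.1 ± 4.7 to 4.07 ± 1.27 FPKM and Col6a3 from 9.09 ± 1.60 to 3.97 ± 0.66. Camera placed both lists lower (adjusted p = 0.00255 for TGF-beta and 0.000678 for matrix), and both calls were lost with an estimated correlation (adjusted p = 0.909 and 0.807), that of matrix also with a replicate block (adjusted p = 0.0931). Fry called neither list as deposited (adjusted p = 0.252 for each). After scaling it called TGF-beta lower (0.0491) and not matrix (0.263).

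Heat-production genes as a group did not pass the set test on the deposited scale (25 tested members, camera adjusted p = 0.170, 0.942 with an estimated correlation), nor after scaling (0.26). With GC and length correction added to scaling the adjusted p was 0.0424, and it was 0.0521 when a replicate block joined that correction. Ucp1, which uncouples respiration to release heat, was at 2256 ± 303 FPKM (SD, n = 3) in wild type and 2723 ± 230 in knockout, a log2 fold change of 0.28 ± 0.15 (SE; limma adjusted p = 0.25) that became 0.61 ± 0.10 after scaling. When adjusted over the list alone Ucp1 was the 1 member that passed after scaling. After a further GC and length correction 4 passed, and before either 0 did. Ucp1 passed over all genes in none of the 3 fits. Elovl3, an elongase typical of cold-stimulated brown fat, was at 23.8 ± 9.96 and 40.1 ± 5.81 FPKM, whereas the regulators Ppara (22.9 ± 5.2 and 12.4 ± 4.8), Ebf2 (3.24 ± 0.55 and 1.99 ± 0.44) and Ppargc1b (17.8 ± 5.0 and 11.7 ± 1.7) were lower in knockout as deposited, none passing the list-alone threshold on that scale. Scaled log2 fold changes were 1.13 for Elovl3, -0.58 for Ppara, -0.32 for Ebf2 and -0.24 for Ppargc1b. Ppargc1b was at -0.0425 after a further GC and length correction. At an unadjusted limma p under 0.05, 1 list member was higher and 3 were lower as deposited. After scaling 6 were higher and 1 was lower. Because camera compares a list with all other genes, a list can be placed higher with a negative median. Respiratory chain subunits were called higher relative to other genes (camera adjusted p = 0.0382, 0.942 with an estimated correlation), although their median log2 fold change was -0.13 as deposited and 0.20 scaled, with 31 of 33 above 0 after scaling. That call was lost with quantile normalization (adjusted p = 0.502), with a replicate block (adjusted p = 0.182), without wild-type library 1 (adjusted p = 0.0952) and without knockout library 1 (adjusted p = 0.853). Fatty acid oxidation genes were not called as deposited (adjusted p = 0.164) and were called higher after scaling (0.00209, adjusted p = 0.558 with an estimated correlation) and without knockout library 3 (0.0292). Of fat-cell markers, Adipoq had a log2 fold change of -0.01 (0.32 scaled, where its sign turned), Lpl of 0.37 ± 0.14 (SE; 0.71 scaled), Pparg of -0.65 ± 0.17 (-0.32 scaled) and Cebpa of -1.03 ± 0.34 (-0.70 scaled), and the pan-adipocyte list (18 tested) was not called (camera adjusted p = 0.644). White fat markers were not called either (adjusted p = 0.296), except without wild-type library 3 (0.015).

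**Figure D3:**
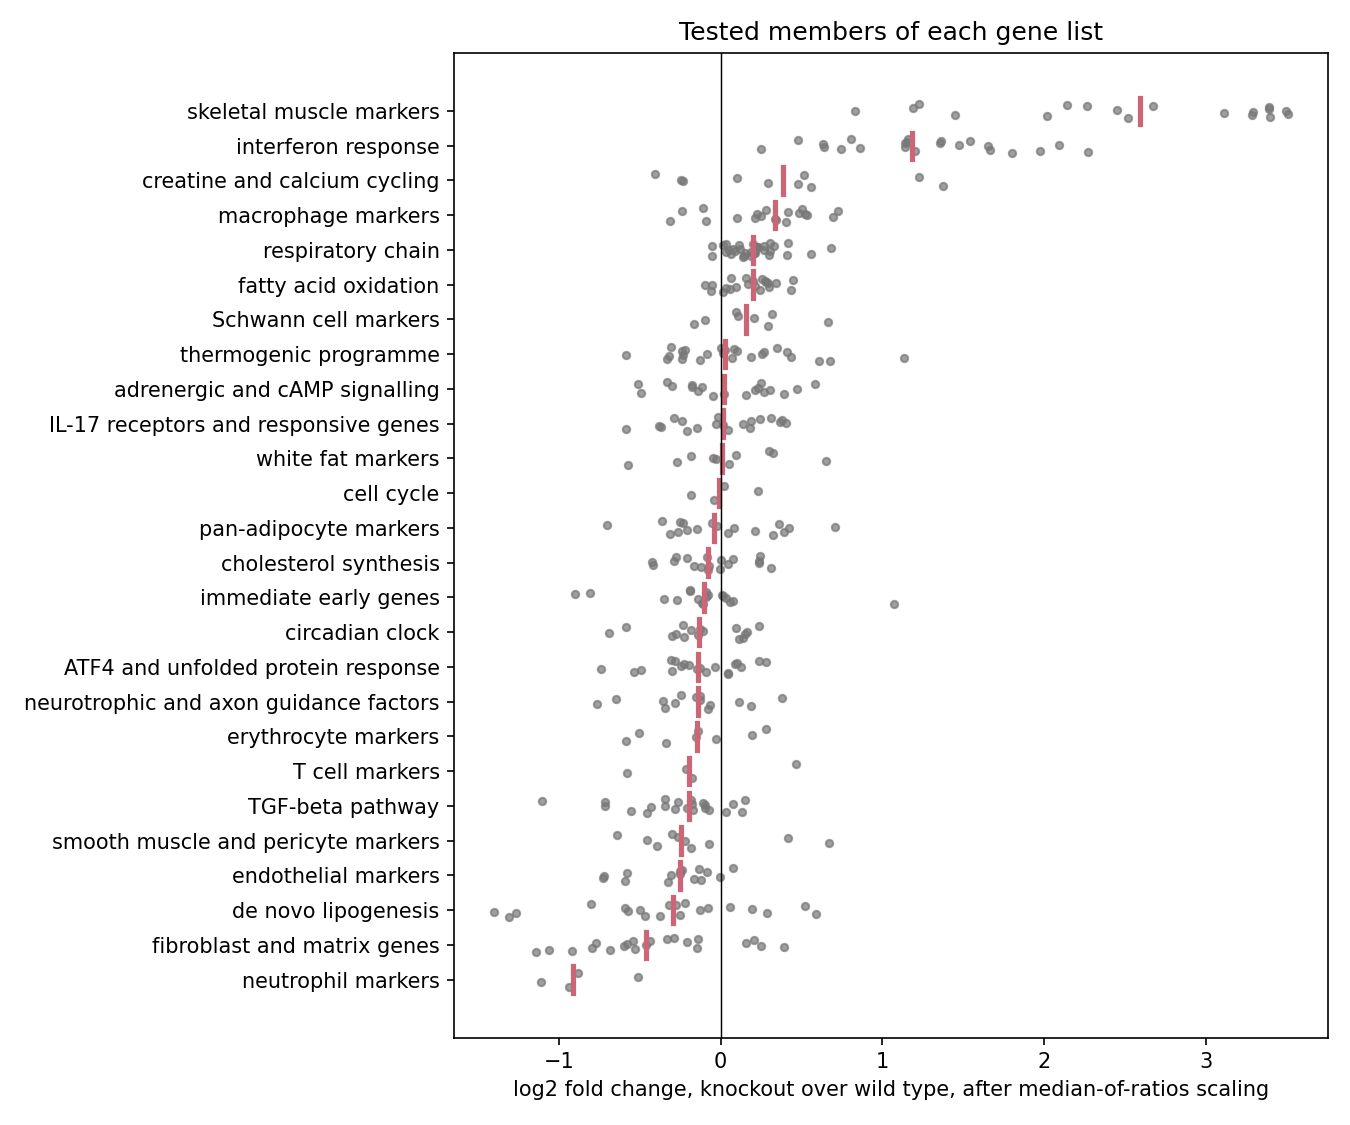
Log2 fold change of knockout over wild type after median-of-ratios scaling (x axis) for the tested members of each gene list with at least 3 (y axis); grey points are genes and red lines are list medians. Skeletal muscle and interferon medians lay farthest to the right (2.59 and 1.18) and neutrophil markers farthest to the left (-0.91).

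Transcripts of nerve fibres lay below the minimum set for the test, a mean of 0.5 FPKM. Th, the rate-limiting enzyme of catecholamine synthesis, was listed at 0 in all 6 libraries. None of the 20 neuron markers reached the expression minimum, so innervation was not compared from these transcripts. Of 14 tested neurotrophic and axon guidance genes, 13 had a negative log2 fold change as deposited and 11 after scaling. As deposited, 9516 of all 10864 tested genes were negative too. Of the 14, 3 fell when adjusted over the list alone (0 after scaling, 0 over all genes). Sema3f, a secreted axon guidance factor, was at 22.5 ± 9.2 FPKM (SD, n = 3) in wild type and 9.97 ± 2.41 in knockout, and its receptor gene Nrp2 at 22.9 ± 9.64 and 10.95 ± 2.06. The list did not pass camera (adjusted p = 0.296). The 8 tested Schwann cell markers were called higher than other genes (camera adjusted p = 0.0382, 0.807 with an estimated correlation) with a median log2 fold change of -0.05. After scaling the adjusted p was 0.26, and it was 0.143, 0.0836, 0.146 and 0.103 without wild-type library 1, wild-type library 2, knockout library 1 and knockout library 2. S100b was at 12.02 ± 2.94 and 15.3 ± 3.3 FPKM and Mbp, a myelin protein gene, at 9.17 ± 3.01 and 6.23 ± 0.35. Adrenergic and cAMP signalling genes were not called (19 tested, adjusted p = 0.464).

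Of the IL-17 receptors and genes that respond to IL-17, none was called as deposited. None of the 19 tested members passed over the list alone or over all genes with limma there, with 0 higher and 4 lower at an unadjusted limma p under 0.05, and the list was not called (camera adjusted p = 0.613 with the direction higher as deposited, 0.733 with the direction lower after scaling). Knockout library 3 stood apart from the other 2: the scaled median of the list was 0.60 log2 units above the wild-type mean there and at -0.29 and -0.0098 in knockout libraries 1 and 2. Without knockout library 3 the direction was lower, with an adjusted p of 0.0515 as deposited and 0.017 after scaling. It was also lower as deposited without wild-type library 3 (0.847). With knockout library 3 as the only knockout library, assumed to vary like wild type, the list was called higher (adjusted p = 0.000213 as deposited, 0.0211 scaled), an alternative chosen after seeing the data. The adaptor gene Traf3ip2 was at 1.41 ± 0.65 FPKM (SD, n = 3) in wild type and 0.56 ± 0.16 in knockout, and Tnfaip3 at 5.20 ± 1.38 and 3.22 ± 0.14. With sample quality weights, which newly called 107 of 121 named genes, Traf3ip2, Tnfaip3, Zc3h12a, Lcn2 and Il17ra passed over all genes as lower (limma adjusted p from 0.00191 to 0.0307). That fit rests mainly on wild-type library 3 and knockout library 2 (weights 4.94 and 6.82, against 0.192 to 0.859 in the others). Neutrophil markers were lower (camera adjusted p = 0.0382, 0.909 with an estimated correlation), and 3 of 4 tested members fell when adjusted over the list alone (2 after scaling). S100a9 was at 36.2, 24.9 and 31.3 FPKM in wild-type libraries 1, 2 and 3 and at 10.9, 6.13 and 19.5 in knockout libraries 1, 2 and 3. S100a8 was at 30.2, 29.4 and 44.2 FPKM in the same wild-type libraries and at 10.3, 7.53 and 33.6 in the knockout ones. Knockout library 3 was next to wild type: its scaled median for the list was -0.11 log2 units from the wild-type mean, against -1.10 and -1.57 in knockout libraries 1 and 2 and -0.11 to 0.15 in wild type. The neutrophil call was lost with a replicate block (adjusted p = 0.0632), without wild-type library 1, 2 or 3 (adjusted p = 0.0952, 0.0544 and 0.0739) and without knockout library 1 (0.173). Macrophage markers were called higher than other genes (camera adjusted p = 1.84e-05, 0.807 with an estimated correlation), with a median log2 fold change of 0.05 (0.33 scaled) and 0 of 19 past the list-alone threshold, and the call was lost without wild-type library 3 (adjusted p = 0.115). Of 21 T cell markers, 4 were tested. Zbtb16 went from 24.3 ± 2.6 to 12.8 ± 1.6 FPKM and fell when adjusted over the list alone. Fry called the list lower after scaling (adjusted p = 0.0491), and camera did not call the list as deposited (adjusted p = 0.696). With no filter, where more of the 21 were tested, its direction turned and it was called higher (adjusted p = 0.0169). Of B cell markers 1 was tested, too few for a set test.

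Other cell types also differed between libraries. Skeletal muscle transcripts were high in knockout libraries 1 and 2: Tcap, a muscle sarcomere gene, was at 9.47 and 13.0 FPKM there, at 0 in knockout library 3 and at 0, 0.06 and 0.61 in wild-type libraries 1, 2 and 3. All 18 tested muscle markers had a positive log2 fold change, 0 passed over the list alone, and the list was called (camera adjusted p = 1.94e-29, 0.502 with an estimated correlation). Creatine and calcium cycling genes were called with them (camera adjusted p = 0.00327, 0.807 with an estimated correlation), and its member Ryr1, the muscle calcium release channel, was at 1.14 and 1.87 FPKM in knockout libraries 1 and 2 and at 0.0049 in knockout library 3. The creatine call was lost after scaling (0.26) and without wild-type library 1 (0.0516), knockout library 1 (0.36) or knockout library 2 (0.422). Endothelial genes were lower (camera adjusted p = 0.0382, 0.942 with an estimated correlation), with 4 of 15 falling when adjusted over the list alone, 4 after scaling and 0 after GC and length correction. Cdh5, the endothelial cadherin, was at 77.2 ± 25.1 FPKM (SD, n = 3) and 39.4 ± 5.4. That call was lost without wild-type library 1 (0.105), wild-type library 2 (0.0576) or knockout library 3 (0.148). Smooth muscle and pericyte markers (adjusted p = 0.464; 4 of 10 fell when adjusted over the list alone, 0 scaled) and erythrocyte markers (0.909) were not called, nor were cholesterol synthesis (0.547), circadian clock (0.303), immediate early (0.924, but 0.00475 without knockout library 1; 2 fell when adjusted over the list alone, 0 scaled), ATF4 and unfolded protein response (0.212) or cell cycle genes (0.92). Among clock genes, which follow the time of collection, Nr1d1 and Bhlhe40 were among the 3 that fell when adjusted over the list alone (0 after scaling).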

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

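Apart from the pseudocounts, filters, scalings, variance models, replicate block, threshold, set tests and single left-out libraries, every alternative here (GC and length correction, scaling combined with another choice, and leaving out knockout libraries 1 and 2 or small RNA features) was chosen after seeing the data. The interferon list was called under each alternative run with a preset correlation (adjusted p from 4.62e-55 to 1.01e-08), and Il17rc was lower in knockout under each alternative run. Pseudocounts of 1 and 0.1 and limma without trend left the call of each of the 121 named genes and 26 lists on its side of the threshold. Newly called named genes were 107 with sample quality weights, 47 after rescaling to a common sum, 10 with robust limma, 16 and 3 without knockout library 3 and wild-type library 2, 7 and 1 after scaling without knockout libraries 3 and 1, and 1 each at a threshold of 0.1 and as deposited without knockout libraries 1 and 2. Numbers in brackets after a gene are log2 fold changes and those after a list are adjusted p-values of the set test. The cause was not tested for any value below, except that fry's turned directions follow from testing a list against no change rather than against other genes, and that left-out features or libraries change what is tested. Where 1 knockout library remains, it is assumed to vary like the wild-type libraries, and the turned or lost muscle and creatine lists follow from leaving out the libraries with the most muscle transcripts. Counts of the highest of repeated symbols were not run, because no symbol was repeated; count-based tests were not run, because the values are FPKM; and robust limma was not run for lists, because camera has no such setting. Depth was only approximated, and values near 0 are not interpretable as counts.

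At a pseudocount of 0.1, the median within-group correlation was 0.952. With no filter, 1 gene was called (1 higher, 0 lower) and the median within-group correlation was 0.984. There the direction of the lists turned for IL-17 receptors and responsive genes (0.759), pan-adipocyte markers (0.803), T cell markers (0.0169) and erythrocyte markers (0.803). Schwann cell markers (0.351), respiratory chain (0.35) and neutrophil markers (0.215) were no longer called. ATF4 and unfolded protein response (0.0452) was newly called, as lower. At a mean FPKM of at least 1, the median within-group correlation was 0.958. Lists that turned direction were immediate early genes (0.969). Schwann cell markers (0.156), creatine and calcium cycling (0.435) and endothelial markers (0.137) were no longer called. With FPKM of at least 0.5 in 3 libraries, the median within-group correlation was 0.977. By set test, directions turned for T cell markers (0.724). Creatine and calcium cycling (0.168) was no longer called. Under median-of-ratios scaling, the log2 fold change turned sign for Adipoq (0.32), Acads (0.0313), Cpt1b (0.0122), Sdha (0.0327), Rrm2 (0.0191) and Pcna (0.23). Turned lists were IL-17 receptors and responsive genes (0.733). Schwann cell markers (0.26) and creatine and calcium cycling (0.26) were no longer called. Fatty acid oxidation (0.00209) was newly called, as higher. Quantile normalization was next, and under it the log2 fold change turned sign for Adipoq (0.12), Rrm2 (0.0446) and Pcna (0.13). The set-test direction turned for thermogenic programme (0.977), IL-17 receptors and responsive genes (0.741) and pan-adipocyte markers (0.203). Schwann cell markers (0.203), respiratory chain (0.502) and creatine and calcium cycling (0.282) were no longer called. Rescaled to a common sum, which Mir6236 raised in knockout library 2, 300 genes were called (51 higher, 249 lower). The median within-group correlation was then 0.956 and Il17rc was at -1.53 with a limma adjusted p of 0.00243. There the direction of the lists turned for pan-adipocyte markers (0.968). Schwann cell markers (0.0997) was no longer called. By robust limma, 14 genes were called (1 higher, 13 lower). By limma with sample quality weights, whose estimation stopped before converging, 6382 genes were called (411 higher, 5971 lower) and Il17rc was at -1.19 with an adjusted p of 0.000935. That fit rests mainly on wild-type library 3 and knockout library 2. Signs then turned for the genes Scn7a (-0.0837) and Rrm2 (0.0505). Lists that turned direction were white fat markers (0.865) and pan-adipocyte markers (0.886). Schwann cell markers (0.0847) and respiratory chain (0.941) were no longer called. Adrenergic and cAMP signalling (0.0374) was newly called, as higher. With a replicate block, 1 gene was called (1 higher, 0 lower) and 7 lists were called (5 higher, 2 lower). De novo lipogenesis (0.158), respiratory chain (0.182), neutrophil markers (0.0632) and fibroblast and matrix genes (0.0931) were no longer called. Camera with an estimated correlation was also run, and 0 lists were called and the interferon list was not called (adjusted p = 0.502). Adding GC and length correction to scaling, the log2 fold change turned sign for Il17ra (0.00945), Adipoq (0.13), Acads (0.11), Cpt1b (0.10), Cox6a1 (0.00628), Sdha (0.0122), Sik1 (0.00353), Sox13 (0.0149), Per1 (0.0211) and Mcm3 (0.0286). By set test, directions turned for IL-17 receptors and responsive genes (0.537) and cell cycle (0.614). Schwann cell markers (0.362) and creatine and calcium cycling (0.059) were no longer called. Thermogenic programme (0.0424) and fatty acid oxidation (0.00623) were newly called, as higher. When a replicate block joined that correction, 1 gene was called (1 higher, 0 lower). Signs then turned for the genes Il17ra (0.00945), Adipoq (0.13), Acads (0.11), Cpt1b (0.10), Cox6a1 (0.00628), Sdha (0.0122), Sik1 (0.00353), Sox13 (0.0149), Per1 (0.0211) and Mcm3 (0.0286). Turned lists were IL-17 receptors and responsive genes (0.508) and cell cycle (0.621). Schwann cell markers (0.418) and creatine and calcium cycling (0.0578) were no longer called. Fatty acid oxidation (0.00317) was newly called, as higher. Erythrocyte markers (0.0496) was newly called, as lower. Scaling together with a replicate block meant that 1 gene was called (1 higher, 0 lower). Signs then turned for the genes Adipoq (0.32), Acads (0.0313), Cpt1b (0.0122), Sdha (0.0327), Rrm2 (0.0191) and Pcna (0.23). The set-test direction turned for IL-17 receptors and responsive genes (0.673). Schwann cell markers (0.219) and creatine and calcium cycling (0.4) were no longer called. Fatty acid oxidation (0.00484) was newly called, as higher. Neurotrophic and axon guidance factors (0.0429) was newly called, as lower. Leaving small RNA features out of the scaled data, 1 gene was called (0 higher, 1 lower) and the median within-group correlation was 0.987. Signs then turned for the genes Adipoq (0.32), Acads (0.0315), Cpt1b (0.0123), Sdha (0.0329), Rrm2 (0.0192) and Pcna (0.23). There the direction of the lists turned for IL-17 receptors and responsive genes (0.728). Schwann cell markers (0.241) and creatine and calcium cycling (0.241) were no longer called. Fatty acid oxidation (0.00179) was newly called, as higher. Scaled and without knockout libraries 1 and 2, which leaves 1 knockout library and takes the spread from wild type alone, 8 genes were called (6 higher, 2 lower). There the log2 fold change turned sign for Il17ra (0.29), Adipoq (0.36), Lcn2 (0.37), Mest (0.00472), Sdha (0.0223), Cd68 (0.14), S100a8 (0.41), Hba-a1 (0.17), Myc (0.10) and Pcna (0.36). Lists that turned direction were thermogenic programme (0.777), pan-adipocyte markers (0.243), creatine and calcium cycling (0.763), adrenergic and cAMP signalling (0.602), skeletal muscle markers (0.475) and erythrocyte markers (0.452). Schwann cell markers (0.763) and neutrophil markers (0.602) were no longer called. IL-17 receptors and responsive genes (0.0211) was newly called, as higher. Smooth muscle and pericyte markers (0.003) was newly called, as lower. As deposited and without knockout libraries 1 and 2, with spread again from wild type alone, 13 genes were called (7 higher, 6 lower). There the log2 fold change turned sign for Scn7a (-0.00165). By set test, directions turned for thermogenic programme (0.886), pan-adipocyte markers (0.321), adrenergic and cAMP signalling (0.599), erythrocyte markers (0.321) and cell cycle (0.967). Schwann cell markers (0.466), respiratory chain (0.562), creatine and calcium cycling (0.967), neutrophil markers (0.886) and skeletal muscle markers (0.818) were no longer called. IL-17 receptors and responsive genes (0.000213) was newly called, as higher. Smooth muscle and pericyte markers (0.0021) was newly called, as lower. After scaling and without wild-type library 1, 4 genes were called (1 higher, 3 lower). There the log2 fold change turned sign for Adipoq (0.16), Pmp22 (0.0508), Hoxc8 (0.0201), Cd68 (0.0317), Mcm3 (0.0849), Rrm2 (0.0594) and Pcna (0.20). Schwann cell markers (0.137) and creatine and calcium cycling (0.303) were no longer called. Fatty acid oxidation (0.00447) was newly called, as higher. After scaling and without wild-type library 2, 4 genes were called (2 higher, 2 lower). Signs then turned for the genes Adipoq (0.40), Acads (0.0866), Cpt1b (0.0783), Sdha (0.0154), Rrm2 (0.0275) and Pcna (0.26). Turned lists were IL-17 receptors and responsive genes (0.568) and white fat markers (0.568). Schwann cell markers (0.383) and creatine and calcium cycling (0.212) were no longer called. Fatty acid oxidation (0.000995) was newly called, as higher. ATF4 and unfolded protein response (0.0405) was newly called, as lower. After scaling and without wild-type library 3, 7 genes were called (1 higher, 6 lower). Signs then turned for the genes Adipoq (0.42), Lep (0.11), Agt (0.18), Cpt2 (0.0303), Acads (0.0494), Cpt1b (0.0248), Sdha (0.11) and Pcna (0.22). The set-test direction turned for IL-17 receptors and responsive genes (0.362) and cell cycle (0.944). Schwann cell markers (0.204), creatine and calcium cycling (0.372) and macrophage markers (0.216) were no longer called. Fatty acid oxidation (0.0026) was newly called, as higher. Neurotrophic and axon guidance factors (0.0283) and immediate early genes (0.0283) were newly called, as lower. After scaling and without knockout library 1, the log2 fold change turned sign for Adipoq (0.33), Sdha (0.0513) and Pcna (0.25). There the direction of the lists turned for pan-adipocyte markers (0.513) and cell cycle (0.959). Schwann cell markers (0.45), creatine and calcium cycling (0.606) and neutrophil markers (0.0628) were no longer called. Fatty acid oxidation (0.0377) was newly called, as higher. Neurotrophic and axon guidance factors (0.0479), smooth muscle and pericyte markers (0.00961) and immediate early genes (0.00158) were newly called, as lower. After scaling and without knockout library 2, 1 gene was called (1 higher, 0 lower). There the log2 fold change turned sign for Adipoq (0.34), Acads (0.0373), Sdha (0.00801), Hba-a2 (0.0311) and Pcna (0.27). Lists that turned direction were erythrocyte markers (0.617) and immediate early genes (0.806). Schwann cell markers (0.492), creatine and calcium cycling (0.934) and neutrophil markers (0.0646) were no longer called. Fatty acid oxidation (0.00668) was newly called, as higher. After scaling and without knockout library 3, 36 genes were called (29 higher, 7 lower), among them the muscle marker Casq1. The sign turned for Adipoq (0.31), Hoxc8 (0.062), Acads (0.0986), Cpt1b (0.14), Ndufv1 (0.00388), Sdha (0.0409), Prkaca (0.00317), Mcm3 (0.0187), Rrm2 (0.11) and Pcna (0.17). By set test, directions turned for IL-17 receptors and responsive genes (0.017) and white fat markers (0.801). Schwann cell markers (0.0956) and macrophage markers (0.102) were no longer called. Fatty acid oxidation (0.000749) was newly called, as higher. Erythrocyte markers (0.0415) and ATF4 and unfolded protein response (0.0325) were newly called, as lower. By fry, which tests a list alone on a scale where the median gene was lower, the interferon list was not called (adjusted p = 0.258) and 0 lists were called. Turned lists were thermogenic programme (0.347), IL-17 receptors and responsive genes (0.408), Schwann cell markers (0.778), white fat markers (0.434), pan-adipocyte markers (0.338), fatty acid oxidation (0.382), respiratory chain (0.434), creatine and calcium cycling (0.97), adrenergic and cAMP signalling (0.338) and cell cycle (0.338).

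Leaving out 1 library at a time on the deposited scale, the lowest and highest values were genes called (3 to 77) and lists called (6 to 11). Fold changes on the log2 scale that turned sign in some of these ranged over Adipoq (-0.0898 to 0.0394) and Scn7a (-0.0297 to 0.20). Adjusted p-values of lists whose direction turned in some ranged over IL-17 receptors and responsive genes (0.0515 to 0.847), white fat markers (0.015 to 0.826), pan-adipocyte markers (0.415 to 0.699), T cell markers (0.524 to 0.876), smooth muscle and pericyte markers (0.0519 to 0.826), erythrocyte markers (0.148 to 0.847), immediate early genes (0.00475 to 0.865) and cell cycle (0.695 to 0.941).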

Other observations

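The tests of each explanation and of the other splits, and the GC and length correction, were chosen only after the results were seen, whereas the gene lists, the scaling and the estimated correlation were fixed before. The 3 patterns weighed are the interferon response, the 2 features past the all-gene test and the genes beside Adipoq.

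The inducible heat-shock genes Hspa1a and Hspa1b, which respond to handling and protein stress, were the 2 immediate early members that fell when adjusted over the list alone (0 scaled). Hspa1a was at 17.8 ± 7.43 FPKM (SD, n = 3) in wild type and 6.99 ± 1.42 in knockout; the pair is nearly identical in sequence, so the split of reads between them is uncertain. Of the pericyte genes, Cspg4 was at 3.51 ± 0.589 and 1.70 ± 0.747 FPKM and Rgs5 at 56.2 ± 2.92 and 38.9 ± 8.43. Gdf15, a stress-induced hormone, was at 5.48 ± 3.10 and 2.22 ± 0.629 FPKM, and Insig1, a regulator of sterol synthesis, at 33.1 ± 11.7 and 19.1 ± 3.83, neither passing over its list.

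GC and length correction did not remove the higher interferon-response genes. With median-of-ratios scaling the list's median log2 fold change was 1.18 (lower quartile 0.82). That outcome was set in advance: the median gene was at -0.29 as deposited, so scaling could only raise the list. The shift lowers deposited values in knockout, so it does not account for a higher list. After a further GC and length correction the list's median was 1.12 (lower quartile 0.75), so that bias does not account for the whole pattern. More macrophages would raise macrophage markers as much, but their scaled median over 19 members was 0.33, with an upper quartile of 0.49 that lay below the lower quartile of the interferon list. By library, macrophage and interferon medians were both lowest in wild-type library 3 (-0.44 and -0.38). Both were highest in knockout library 2 (0.42 and 0.99) and knockout library 3 (0.54 and 2.01). They parted in wild-type library 1 (0.25 and -0.03), wild-type library 2 (0.08 and 0.52) and knockout library 1 (0.09 and 0.73). A smaller share from macrophages therefore stays open. A difference in infection status, housing or litter between the groups remains open and untested, as does the knockout itself, and the loss of the call with an estimated correlation (adjusted p = 0.502) limits any reading.

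Apoo-ps and Snord32a have properties that may reflect how reads were assigned. Scaled Apoo, the parent gene, was higher in knockout by 1.04 ± 0.37 log2 units (SE), under 0.05 before and not after adjustment by limma (adjusted p = 0.254), the direction that reads listed under Apoo-ps in wild type and under Apoo in knockout would give. Of 42 tested small nucleolar RNA features, 17 (40.5%) held both a 0 and a value above 10 FPKM within a group, which leaves open whether the zeros of Snord32a are of that kind. The sum of Apoo and Apoo-ps, which differ in length, overlapped between the groups as deposited (83.4 to 89.7 FPKM in wild type, 82.8 to 90.8 in knockout) and not after scaling (67.4 to 82.2 and 90.5 to 101). In wild-type libraries 1, 2 and 3 Apoo was at 31.6, 59.9 and 76.2 FPKM, rising as Apoo-ps fell (58.1, 23.5 and 10.2). Their sum there stayed at 89.7, 83.4 and 86.4 FPKM. This exchange within wild type argues for reads shared between Apoo and Apoo-ps. The knockout itself stays open for Snord32a, and for why the split between Apoo and Apoo-ps differed between the groups.

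Kng1, Kng2, Eif4a2 and Rfc4 lie beside Adipoq in the GRCm38 gene order, and all but Kng1 were chosen after their values were seen. Their scaled log2 fold changes were 1.28, 0.45, 0.74 and 0.53 (1.17, 0.34, 0.43 and 0.22 after GC and length correction), whereas Fetub and St6gal1 in the same window were at -0.35 and -0.23. A candidate explanation was extra copies of the region around Adipoq, which a transgene with an Adipoq promoter might carry; the labels name no such driver. The test could not decide this, because its window of 10 genes reaches past these neighbours and would dilute a shorter stretch. The 10 nearest tested genes had a median of 0.18, and 7.94% of 10356 such windows were at least as high (48.6% for the window around Il17rc). After GC and length correction the share was 6.87%, and Eif4a2 and Rfc4 moved most towards 0, so that bias stays open too.

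The tests were repeated on each split of the 6 libraries into 3 and 3. Of the 10 splits, the real one included, 5 called as many genes (2 in the real split, 4 in the highest other), 4 did so after scaling (2 and 4), and 3 called as many lists (11 and 17). With 10 splits no share under 0.05 can be reached. The split with 17 lists set knockout libraries 1 and 2 with wild-type library 3, the libraries with the most skeletal muscle transcripts, against the rest, which points to a structure of the samples other than genotype.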
